A study of Homo sapiens with 36 samples.

How the data were processed

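Labelled cytoplasmic RNA of U2OS cells was sequenced before and after an m6A immunoprecipitation. The tools and build extracted from the submitters' processing notes were Trim Galore, Bowtie2, RSEM version 1.3.0 and human build hg19. Their order and settings were not examined here. The names of both deposited tables call the values TPM per isoform, a unit scaled to the same total in every library, which keeps no depth. That unit was not examined here, because the values were not used.

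All 36 per-library value columns were left out. Their names are running numbers. A search of the titles, descriptions, source names, characteristics and the growth, treatment and extraction protocols, ignoring case, spaces and punctuation, found none of them. The full text of the processing notes was not searched, so a key to the columns there is not excluded. Columns were not assigned by their order or by their values. The 13 results and 177 alternatives planned before the data were examined were consequently not computed. Several of the 13 were counts in opposite directions from the same fit. Groups were taken from the sample titles.

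The identifier and symbol columns were read with Python 3.11.15 and pandas 2.3.3. In the table named for repeat 1, 25 lines held a pair of records with no line break between them, and 24 lines did so in the table named for repeat 2. Each was split at the RefSeq accession that follows the last value of the first record. Records without a symbol were named through a RefSeq gene table of assembly GRCh38.p14, by accession without version and without the copy number that 1363 of those identifiers carried. Only names were taken from that table, and no coordinates. For 4033 records the deposited symbol differed from the one in the RefSeq table, and the deposited one was kept. The 24 gene lists were matched on exact symbols or on a fixed symbol pattern.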

Results

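The series set out to ask whether newly made mRNAs that carry N6-methyladenosine (m6A, a methyl mark on adenosine) and unmethylated copies of the same mRNAs are lost from the cytoplasm at different rates. The cells were U2OS, an established human osteosarcoma line. RNA made during 2 h of labelling was marked with bromouridine (BrU), a uridine analogue that an antibody can capture, and cytoplasmic RNA was taken at 0, 0.5, 1, 2, 4 and 6 h after BrU was removed. The captured RNA was then passed over an m6A antibody.

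The labels name 36 libraries from 2 biological repeats. They fall into 3 fractions, titled input, IP and FT, with 12 libraries each. With 6 times, this gives 18 groups of 2 libraries. The design implies comparisons of IP with FT, of times within a fraction, and of the time course of IP with that of FT.

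The deposited values are in 2 tables, one named for each repeat, with 18 value columns each. The 36 columns are named only by a running number. No title, description, source name, characteristic, or growth, treatment or extraction protocol holds any of these names. The full text of the processing notes was not searched for them. A column was therefore tied to no fraction and no time, and none of the comparisons above was made. Order alone was not taken as a link between a column and a library. No level, fold change or rate of loss is given for any gene, and the depth of the libraries is unknown here.

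The columns that name the transcripts belong to no library and were described. Each table lists 52002 isoform records, and all 52002 identifiers were shared by both tables. Of these, 39880 carry the RefSeq prefix for mRNA and 12120 the prefix for non-coding RNA, with 2 records outside both. The deposited gene symbol was present for 46879 records and absent for 5123. A RefSeq gene table held the accession of 4910 of the 5123, which left 213 unnamed. After this step the records carried 26523 distinct symbols, of which 15908 had 1 record and 10615 had 2 or more. Of the 5123 records without a deposited symbol, 1363 have a copy number after the accession. How many of the 46879 records with a deposited symbol have one was not determined. Each copy was counted as a record, so several records of a gene need not be different isoforms. Old and current symbols of one gene can both be among them.

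Genes from 23 of the 24 lists chosen before the data were examined were named in the tables. The list of m6A writers, erasers and readers, which covers the enzymes that set or remove the mark and the proteins that bind it, had 23 named genes with 60 isoform records. The list of deadenylation and decay factors, which shorten poly(A) tails or degrade mRNA, had 38 genes with 98 records. Immediate-early genes, which respond fast to stimulation, had 42 genes with 78 records. Cytokine and other mRNAs with AU-rich elements had 33 genes with 76 records. Ribosomal protein genes numbered 86 with 154 records. The C2H2 zinc finger list, matched by ZNF symbol and not checked for the domain, had 528 genes with 1211 records. The list of mitochondrially encoded genes had 0 named genes. These counts describe the annotation and say nothing about expression. A list member held only under another symbol was not counted. List sizes are not given, so the coverage of a list cannot be judged from them.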

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

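The settings here were chosen after the files were seen and concern the annotation alone. The table named for repeat 1 held 52002 records with joined lines split and 51952 with them left out. Its distinct symbols numbered 26523 with the RefSeq names, 26512 without the joined lines and 24995 with the deposited symbols alone. The table named for repeat 2 gave 52002 records and 26523 symbols. These counts had to match, because both tables share all identifiers and 0 symbols differ between them. The 177 alternatives planned for the comparisons were not run, since no comparison was made. No paired analysis was possible because no value column was tied to a fraction or a time. The titles do pair the input, IP and FT libraries by repeat and time, and each table is named for one repeat.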
